A study of Danio rerio with 4 samples.

How the data were processed

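Gene expression was measured in zebrafish larvae at 120 hours post fertilization on 1-colour Affymetrix zebrafish arrays, with 2 uhrf1 mutant and 2 wildtype samples. Total RNA had been extracted with TRIzol and labelled with biotin, per the labels' protocols. One protocol line of the labels gives the age in days, while the source label and the design text give hours, and hours were used here. The deposited values are intensities per probe set that the authors made with RMA, per the submitters' processing notes. RMA corrects the background, quantile-normalizes the probes of all arrays together and summarises them per probe set. Its version, software and settings are not given in the sources used here. The intensities were deposited on a linear scale, from 4.48 to 17601 over the probe sets tested, and they carry no detection calls. RMA compresses changes near background and near saturation, so folds of dim and of very bright genes are understated.

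The table held 15617 probe sets, of which 115 array controls were left out of every test, leaving 15502. A table of platform annotation named exactly 1 gene for 10795 of these, several for 135 and none for 4572. Symbols were updated through the Entrez gene ID for 10718 of the 10802 single-gene probe sets of that table, controls included, and the older symbol was kept for 84. Each of the 8793 genes was represented by the probe set with the highest mean over all 4 arrays, a choice blind to the group. Probe sets without exactly 1 gene symbol were tested but not named. The array measures probe sequences and no genome coordinates were used here.

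Values were taken as log2(intensity + 1) and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with 1 prior variance), with mutant against wildtype as the only term. The fit had 2 residual and 4.04 prior degrees of freedom. All p-values for genes are two-sided limma p-values with Benjamini-Hochberg adjustment over the 15502 probe sets, and a gene was called at an adjusted p under 0.05. Log2 changes are mutant minus wildtype on the log2(intensity + 1) scale with the moderated standard error, and folds are ratios of the group means of the deposited intensities. Group values are means ± SD of 2 arrays. The number of arrays limits the precision.

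The 29 gene lists were written before the data were examined, as were the design, the rule for named genes and the alternatives, except 2 that are named as added. They cover the DNA methylation machinery, DNA replication, mitosis, p53 targets, DNA damage repair, apoptosis, interferon and antiviral genes, inflammation and acute phase, hepatocytes, exocrine pancreas, islets, enterocytes, photoreceptors, lens, retinal progenitors, neurons, muscle, cartilage, erythrocytes, myeloid cells, lymphoid cells and thymus, epidermis, germ cells, endoplasmic reticulum stress, heat shock and oxidative stress, cholesterol synthesis, ribosomal proteins, pigment cells and one-carbon metabolism. Of 1117 genes in any list, 693 were on the array under a symbol that could be matched. Lists were tested on the gene-level values with camera at a preset correlation of 0.01, two-sided, with adjustment over the 29 lists. Camera with an estimated correlation and fry, a rotation test of whether a list's genes move one way on balance, were alternatives. Counts "adjusted over the list alone" use limma p-values adjusted within that list.

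The rule for named genes was uhrf1, the 8 largest rises and the 8 largest falls among called genes whose mutant and wildtype arrays did not overlap, and up to 3 members with the smallest p from each list that was called, or 1 from a list that was not. Genes outside the rule are marked where they are named.

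The fit was tested on simulated data for the comparison of mutant with wildtype, with 15502 probe sets drawn from the wildtype means and the fitted prior of the variance, 200 of them changed. It called 17 of 60 probe sets changed by 1 on the log2 scale, 62 of 69 changed by 2 and 70 of 71 changed by 4, all in the right direction, with 8 false calls among 157. With no change simulated it made 0 calls. A simulated shift of -1 in the exocrine list alone, with errors independent between genes, was called by camera with the preset correlation. The estimated correlation gave it a camera adjusted p of 0.38, so with 2 residual degrees of freedom that setting did not call this simulated shift. The measured exocrine list had an estimated correlation of 0.62, so the simulation does not show that the preset correlation is right for the measured lists.

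Alternatives were quantile normalization and median centring of the deposited values, a filter that removed the dimmest 25% of probe sets, an intensity-dependent robust prior, a pseudocount of 16, the mean of all probe sets of a gene, other thresholds, an unmoderated model, and leaving out each array in turn. Scaling on the 18 hybridisation control probe sets and a shortened myeloid list were added after seeing the data. No paired analysis was possible because the groups share only 1 replicate number in the labels.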

Results

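Whole-larva gene expression was compared between zebrafish with a mutation in uhrf1 and wildtype larvae at 120 hours post fertilization. UHRF1 is the protein that binds hemimethylated DNA at replication forks and brings the maintenance methyltransferase DNMT1 to it. The labels' growth protocol describes offspring of heterozygous carriers of a uhrf1 allele for most of the study's experiments. There were 2 mutant samples (replicates 1 and 2) and 2 wildtype samples (replicates 1 and 3). The labels do not say whether a sample was 1 larva or a pool, nor that replicates came from separate clutches, so p-values measure only the spread between these samples, which may be technical.

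The 4 arrays had median intensities between 29.4 and 31.5 over the 15502 probe sets. The Pearson correlation of log2 values across probe sets was 0.987 between the mutant arrays and 0.989 between the wildtype arrays, against 0.969 to 0.975 between groups. The median absolute log2 difference did not part the groups, at 0.174 between the mutant arrays, 0.157 between the wildtype arrays and 0.157 to 0.205 between groups. Genes are not independent replicates, so these describe the arrays only. The 18 hybridisation control probe sets, bacterial and phage transcripts added in fixed amounts before hybridisation, were on average 0.49 lower on the log2 scale on the mutant arrays. Of these, 17 were lower on both mutant arrays than on both wildtype arrays. Several of them measure the same added transcript and all move together within an array, so the count is not independent evidence. For a single probe set chance gives this order in 16.7% of cases. The median log2 change of all probe sets was -0.04 as deposited and 0.45 when arrays were scaled on these controls. Every change below is therefore relative to the bulk of the array. The controls changed by -0.82 to -0.06, so they give no single scale factor, and they do not measure the amount of RNA per larva. The absolute direction of changes, above all of those smaller than about 0.49, is not fixed by the data.

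The uhrf1 transcript itself was examined first. The brighter of its 2 probe sets read 33.7 ± 10.5 (SD, n = 2) in mutants and 44.5 ± 4.19 (SD, n = 2) in wildtype larvae, a log2 change of -0.42 ± 0.23 (SE) with a limma adjusted p of 0.56. Both mutant arrays, at 41.1 and 26.3, lay below both wildtype arrays, at 47.4 and 41.5. The other probe set read between 8.97 and 9.91 on all 4 arrays, under the 12.6 that bounds the dimmest 25% of probe sets, with a log2 change of -0.04 ± 0.13 (SE). The sign of the first change was not fixed either, as it was 0.07 with arrays scaled on the hybridisation controls. Where these probes lie relative to the mutation is not given in the sources used here, so the level of uhrf1 neither bears out nor contradicts the labels.

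By limma, mutant larvae differed from wildtype larvae in 176 genes, of which 91 rose and 85 fell. Of the 29 gene lists fixed beforehand, the interferon and antiviral list had the highest median log2 change, 1.77, and the exocrine pancreas list the lowest, -3.31. With an estimated correlation camera's adjusted p was 0.28 for each. That setting called 0 of the 29 lists, and it did not call the simulated shift of -1 either. Its p-values below therefore do not argue against a list's shift. Of the 176 genes, 153 changed by at least 1 on the log2 scale. At an unadjusted limma p under 0.05 there were 1294 genes. Without mutant replicate 1 the count was 113 genes, 43 of them lower, and without mutant replicate 2 it was 122, with 54 lower. Scaling on the hybridisation controls gave 2754 higher and 79 lower genes, so 97.2% of the calls were higher there against 51.7% as deposited. The unmoderated model, with 2 residual degrees of freedom, called 0 genes, with 868 at an unadjusted p under 0.05.

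**Figure D1:**
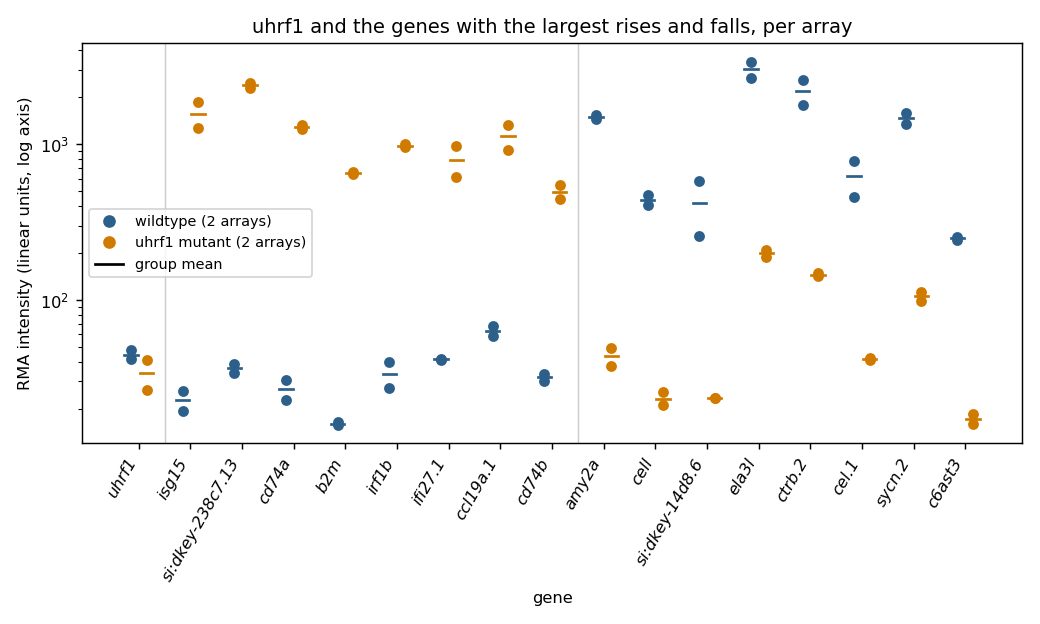
RMA intensity per array (linear units on a log axis) of uhrf1 and of the 8 genes with the largest rises and the 8 with the largest falls, with 2 wildtype arrays (blue) and 2 mutant arrays (orange) as points and group means as short lines. For isg15 the mutant mean was 1557 and the wildtype mean 22.7, for amy2a the means were 43.5 and 1500, and the uhrf1 arrays lay between 26.3 and 47.4.

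The largest rise was in isg15, a ubiquitin-like protein induced by interferon, which read 1557 ± 421 (SD, n = 2) in mutants and 22.7 ± 4.58 (SD, n = 2) in wildtype larvae. This is a 68.7-fold ratio of means and a log2 change of 6.03 ± 0.23 (SE), with a limma adjusted p of 0.00030. The uncharacterised gene si:dkey-238c7.13 rose 65.8-fold, to 2395 ± 124 (SD, n = 2). The invariant chains of MHC class II, cd74a and cd74b, rose by 5.56 ± 0.18 and 3.90 ± 0.16 (SE, log2), and b2m, the light chain of MHC class I, by 5.26 ± 0.13 to 651 ± 15.5 (SD, n = 2) intensity units. The interferon regulatory factor irf1b rose 29.3-fold, the interferon-inducible gene ifi27.1 19.2-fold and the chemokine gene ccl19a.1 17.7-fold. MHC, CD74 and ifi27 genes belong to families whose members can cross-hybridise. Several of these genes sat near the dim end of the array in wildtype larvae, where RMA understates folds.

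In the interferon and antiviral list, 10 of 18 measured genes rose, none fell and 8 did not pass, with a median log2 change of 1.77, and 14 rose adjusted over the list alone. Beside b2m and isg15, irf7, a master regulator of type I interferon, rose 11.2-fold to 315 ± 7.13 (SD, n = 2) with an adjusted p of 0.00030 by limma. Some interferon genes did not pass: mxa, an antiviral GTPase, changed by 0.10 ± 0.22 and irf1a by -0.01 ± 0.13 (SE, log2). Both read close to the 12.6 that bounds the dimmest 25% of probe sets, and both were chosen after their values were seen. Camera called the list upward with an adjusted p of 2.4e-25 at the preset correlation. With an estimated correlation its adjusted p was 0.28, and fry gave an adjusted p of 0.049. The hybridisation controls, lower by 0.49 on the mutant arrays, moved against this list, whose median became 2.26 when scaled on them. Between 9 and 11 members rose when any 1 array was left out, 5 rose with a pseudocount of 16 and 16 when scaled on the controls.

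In the inflammation and acute-phase list 10 of 22 measured genes were higher, none was lower and 12 did not pass, with a median of 0.80. The list's camera adjusted p was 2.5e-15, and the adjusted p with an estimated correlation was 0.28. There were 13 higher and 2 lower genes adjusted over the list alone, the lower ones being hp and lgals2b, named after their values were seen. The suppressors of cytokine signalling socs3a and socs3b rose 6.60-fold and 3.98-fold, and the AP-1 gene junba rose 3.20-fold, with limma adjusted p-values of 0.0011, 0.0021 and 0.0036. In the myeloid list 4 of 23 measured genes rose, none fell and 19 did not pass, and adjusted over the list alone 6 rose. The 4 were cd74a, cd74b and ccl19a.1, which serve antigen presentation and chemotaxis, and the matrix metalloprotease mmp9, which the inflammation list also holds and which rose by 2.73 ± 0.23 (SE, log2). Camera called the myeloid list upward with an adjusted p of 4.6e-08, and its adjusted p with an estimated correlation was 0.35. Of the inflammation list 7 were higher and 1 lower without mutant replicate 2, 4 were higher with a pseudocount of 16, and 16 were higher and 1 lower with arrays scaled on the hybridisation controls, where 17 myeloid genes were higher. Without 5 antigen-presentation, chemokine and metalloprotease genes the myeloid list's median was 0.15 and its camera adjusted p at the preset correlation 0.0098. An estimated correlation was not tried on this shortened list. With a pseudocount of 16 the median of the full myeloid list was 0.11.

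Genes of the exocrine pancreas fell together: 15 of 17 measured genes were lower, none was higher and 2 did not pass, with a median log2 change of -3.31, and 16 were lower adjusted over the list alone. Pancreatic amylase, amy2a, fell 34.5-fold from 1500 ± 64.9 to 43.5 ± 8.19 (SD, n = 2 each), a log2 change of -5.09 ± 0.17 (SE) with a limma adjusted p of 0.00030. The carboxypeptidase gene cpb1 fell 9.35-fold, the zymogen granule gene sycn.2 13.9-fold, the elastase gene ela3l 15.2-fold, the chymotrypsinogen gene ctrb.2 15.1-fold and the bile salt-stimulated lipase gene cel.1 14.8-fold. Outside the list, the 8 largest falls also held its relative cell, by 18.9-fold, the astacin-like protease gene c6ast3, by 14.4-fold, and si:dkey-14d8.6, by 17.9-fold. Of the 2 that did not pass, the acinar transcription factor gene ptf1a changed by -0.34 ± 0.13 (SE, log2) between 20.8 and 16.2 intensity units, and ela2l differed widely between arrays of 1 group, at 115 ± 98.7 and 485 ± 485 (SD, n = 2 each). Proteases of these families can cross-hybridise. For the exocrine list camera's adjusted p was 9.7e-33, the adjusted p with an estimated correlation was 0.28, and fry's was 0.049. The hybridisation controls moved in the same direction by 0.49, and with arrays scaled on them the median was -2.82 and 15 genes fell. With any 1 array left out, 13 to 16 fell.

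In the enterocyte list 3 of 24 measured genes fell, none rose and 21 did not pass, and the median was -0.81. The list's camera adjusted p was 5.2e-05, and its adjusted p with an estimated correlation was 0.44. With p-values adjusted over the list alone, 12 fell and 1 rose. The fatty acid and bile acid binding proteins fabp2 and fabp6 fell 5.38-fold and 3.49-fold, and the meprin protease gene mep1a.1 fell to 48.2 from 116 intensity units, with limma adjusted p-values of 0.031, 0.010 and 0.043. The count was 5 without mutant replicate 2, 7 without wildtype replicate 1 and 5 without wildtype replicate 3, where the median was -0.53, and 0 with a pseudocount of 16. With arrays scaled on the hybridisation controls the enterocyte median was -0.32, with 4 genes lower and 3 higher. Islet genes were not called as a list, with 0 of 12 passing in limma, a median of -0.14 and a camera adjusted p of 0.27. At an unadjusted p under 0.05 there were 4, of which 1 was higher and 3 were lower, and 3 islet genes were lower adjusted over the list alone. The islet median was 0.01 without mutant replicate 1 and -0.33 without mutant replicate 2. The islet list was past the threshold with a camera adjusted p of 0.044 without mutant replicate 2 and of 0.043 with arrays scaled on the controls, where 4 islet genes were higher, none was lower and its median of 0.35 lay below the 0.45 of all probe sets.

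Hepatocyte products moved in both directions. Of 45 measured genes 3 rose, 5 fell and 37 did not pass, and adjusted over the list alone 10 rose and 13 fell. The complement gene c4b rose 7.22-fold with a limma adjusted p of 0.0013. The other called genes, named because their number is small and after their values were seen, were the fibrinogen chains fgb and fgg, which rose by 1.87 ± 0.27 and 1.65 ± 0.23 (SE, log2), and hpda, hgd, uox, tdo2a and agxta, whose log2 changes were -1.71, -1.56, -2.55, -1.61 and -0.87. hpda and hgd act in tyrosine breakdown, tdo2a in tryptophan breakdown, uox in urate breakdown and agxta in glyoxylate metabolism. The list as a whole was not called, with a median of -0.09 and a camera adjusted p of 0.98, as camera tests for a shift one way. Fry's mixed test, which asks whether a list's genes move in either direction, was not among the alternatives above. Its adjusted p was 0.00042 for the hepatocyte list. Counts were 5 higher and 2 lower without mutant replicate 1, 3 and 7 without mutant replicate 2, 5 and 6 without wildtype replicate 1, and 5 and 4 without wildtype replicate 3, and 1 and 1 with a pseudocount of 16. Scaled on the controls, 17 were higher and 5 lower, and camera called the list downward relative to the other genes with an adjusted p of 2.0e-05.

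The photoreceptor, retinal progenitor and lens lists were called downward relative to the other genes at the preset correlation, with 1, 0 and 0 genes passing. They were not called with an estimated correlation, which called 0 of the 29 lists, and their adjusted p-values there were 0.28, 0.28 and 0.56. The lens call was also lost in 2 of the 4 fits with 1 array left out. In the photoreceptor list 1 of 36 measured genes fell and 35 did not pass, with a median of -0.48, and 29 of the 36 values lay below 0. There were 15 lower genes adjusted over the list alone. The cone transducin subunit gngt2a fell 2.95-fold with a limma adjusted p of 0.030. The retinoid-binding protein gene rbp3 changed by -1.52 ± 0.27 and the cone signalling regulator rgs9a by -1.02 ± 0.18 (SE, log2), with adjusted p-values of 0.067 and 0.068 by limma. The photoreceptor list's camera adjusted p was 2.4e-06, and the adjusted p with an estimated correlation was 0.28. Without mutant replicate 2 there were 0 photoreceptor genes past the threshold, while 2 passed without wildtype replicate 1 and 3 without wildtype replicate 3, and 0 with a pseudocount of 16. In the retinal progenitor list 0 of 20 genes passed in limma (8 at an unadjusted p under 0.05), 18 values lay below 0 and the median was -0.44, with a camera adjusted p of 0.00027 and an adjusted p of 0.28 with an estimated correlation. Its proneural genes ascl1a and ascl1b changed by -0.68 ± 0.13 and -0.87 ± 0.18 and the eye-field gene pax6b by -0.65 ± 0.16 (SE, log2), and 2 of its genes were lower adjusted over the list alone and 2 without wildtype replicate 1. Among lens genes 0 of 14 passed in limma (4 at an unadjusted p under 0.05) and the median was -0.18. The lens filament gene bfsp2 changed by -0.70 ± 0.13 and the crystallins crybb1 and crygm2c by -0.80 ± 0.17 and -0.90 ± 0.24 (SE, log2), and adjusted over the list alone 4 lens genes were lower. The lens list's camera adjusted p was 0.018, 0.061 without mutant replicate 1 and 0.12 without wildtype replicate 1, where the lens medians were -0.09 and -0.11 (-0.29 without wildtype replicate 3), and the adjusted p with an estimated correlation was 0.56. Scaled on the hybridisation controls, the photoreceptor, retinal progenitor and lens medians were 0.01, 0.05 and 0.31, each below the 0.45 of all probe sets, with 4 higher and 2 lower, 1 higher and 2 higher genes. With a pseudocount of 16 these medians were -0.41, -0.21 and -0.10.

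The DNA replication, p53 target and apoptosis lists were called upward relative to the other genes at the preset correlation without any gene passing. They were not called with an estimated correlation, which called 0 of the 29 lists, at adjusted p-values of 0.56, 0.28 and 0.44. Fry did not call them either, at 0.46, 0.058 and 0.31. The mitosis list was not called, with a median of -0.03, 17 values above 0 and a camera adjusted p of 0.41. In the DNA replication list 0 of 44 genes passed in limma (9 at an unadjusted p under 0.05), 29 values lay above 0 and the median was 0.10. The replicative helicase genes mcm5 and mcm4 changed by 0.57 ± 0.14 and 0.62 ± 0.16 and cdca7a by 0.70 ± 0.17 (SE, log2), with limma adjusted p-values of 0.15, 0.18 and 0.16. The replication list's camera adjusted p was 0.00022, 0.051 without mutant replicate 1, and the adjusted p with an estimated correlation was 0.56. The count adjusted over the list alone was also 0. The replication median was 0.04 without mutant replicate 1, 0.19 without mutant replicate 2, where 1 gene passed, and 0.05 without wildtype replicate 3, and 24 genes were higher with arrays scaled on the hybridisation controls. In the p53 target list 0 of 24 genes passed in limma, and 11 did at an unadjusted p under 0.05, 9 of them higher and 2 lower. Of the 24 values 16 lay above 0 and the median was 0.34, and adjusted over the list alone 8 were higher. phlda3, gadd45aa and the initiator caspase gene casp8 changed by 0.75 ± 0.14, 0.91 ± 0.17 and 0.93 ± 0.17 (SE, log2), with limma adjusted p-values of 0.072, 0.074 and 0.077. The apoptosis list also holds casp8 and baxa, so these lists are not fully separate. Camera's adjusted p for p53 targets was 0.00027, and the adjusted p with an estimated correlation was 0.28. With arrays scaled on the hybridisation controls, camera's adjusted p at the preset correlation was 0.059 for the p53 list and 0.055 for the apoptosis list, with 14 and 13 genes higher. Without mutant replicate 2 the p53 median was 0.21, and 1 p53 gene was higher without each of the other arrays, with 1 lower without wildtype replicate 1. In the apoptosis list 0 of 19 genes passed in limma, and 4 did at an unadjusted p under 0.05, 3 of them higher and 1 lower. The median was 0.27, and adjusted over the list alone 2 were higher. Cell death itself was not measured. The inflammatory caspase gene caspb changed by 0.75 ± 0.13 and bada, a pro-apoptotic Bcl2 relative, by -0.45 ± 0.17 (SE, log2), or 0.04 when scaled on the controls. The apoptosis list's camera adjusted p was 0.0043, 0.11 without mutant replicate 2, and its median was 0.11 there and 0.12 without wildtype replicate 1, while 0.44 was its adjusted p with an estimated correlation.

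In the endoplasmic reticulum stress list 2 of 25 measured genes rose, none fell and 23 did not pass, with a median of 0.40, and adjusted over the list alone 8 rose. The stress list's camera adjusted p was 4.6e-07, and the adjusted p with an estimated correlation was 0.31. The stress transcription factor gene atf3 rose 3.69-fold and the disulfide isomerase gene pdia4 2.89-fold, with limma adjusted p-values of 0.0059 and 0.049, while the chaperone gene hyou1 changed by 0.86 ± 0.14 (SE, log2) at 0.050. With mutant replicate 1 or mutant replicate 2 left out 1 gene of this list passed, and 3 did without wildtype replicate 1, 1 with a pseudocount of 16 and 17 when scaled on the controls. In the cholesterol synthesis list all 12 values lay below 0 with a median of -0.38, and 1 gene, the sterol reductase dhcr7, fell 1.81-fold with a limma adjusted p of 0.049, and 2 were lower adjusted over the list alone. With quantile normalization or median centring 0 genes of this list passed. Of the fits with 1 array left out, that without wildtype replicate 1 gave 1 lower gene and the others 0, as did a pseudocount of 16. msmo1 and fdps, which act earlier in the pathway, changed by -1.04 ± 0.24 and -0.39 ± 0.13 (SE, log2), the second at 0.10 when scaled on the hybridisation controls. For sterol genes camera's adjusted p was 0.00026, and the adjusted p with an estimated correlation was 0.35. With arrays scaled on the hybridisation controls the median of this list was 0.11, below the 0.45 of all probe sets, and 0 of its genes passed. Muscle genes had a median of 0.15 and a camera adjusted p of 0.018 upward, with an adjusted p of 0.79 with an estimated correlation. The only one of 32 that passed, the desmin gene desmb, fell 1.86-fold, and the count adjusted over the list alone was also 1. With quantile normalization, where the median was 0.25, or median centring 0 muscle genes passed. With any 1 array left out, and with a pseudocount of 16, 0 muscle genes passed, while 17 were higher and 0 lower with arrays scaled on the hybridisation controls. acta1a and tnnc2.2 changed by -0.51 ± 0.15 and 0.37 ± 0.13 (SE, log2). The muscle list's adjusted p was 0.41 without mutant replicate 1 and 0.49 without wildtype replicate 3, where the medians were 0.07 and 0.04 (0.27 without wildtype replicate 1), and 0.31 when scaled on the controls.

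**Figure D2:**
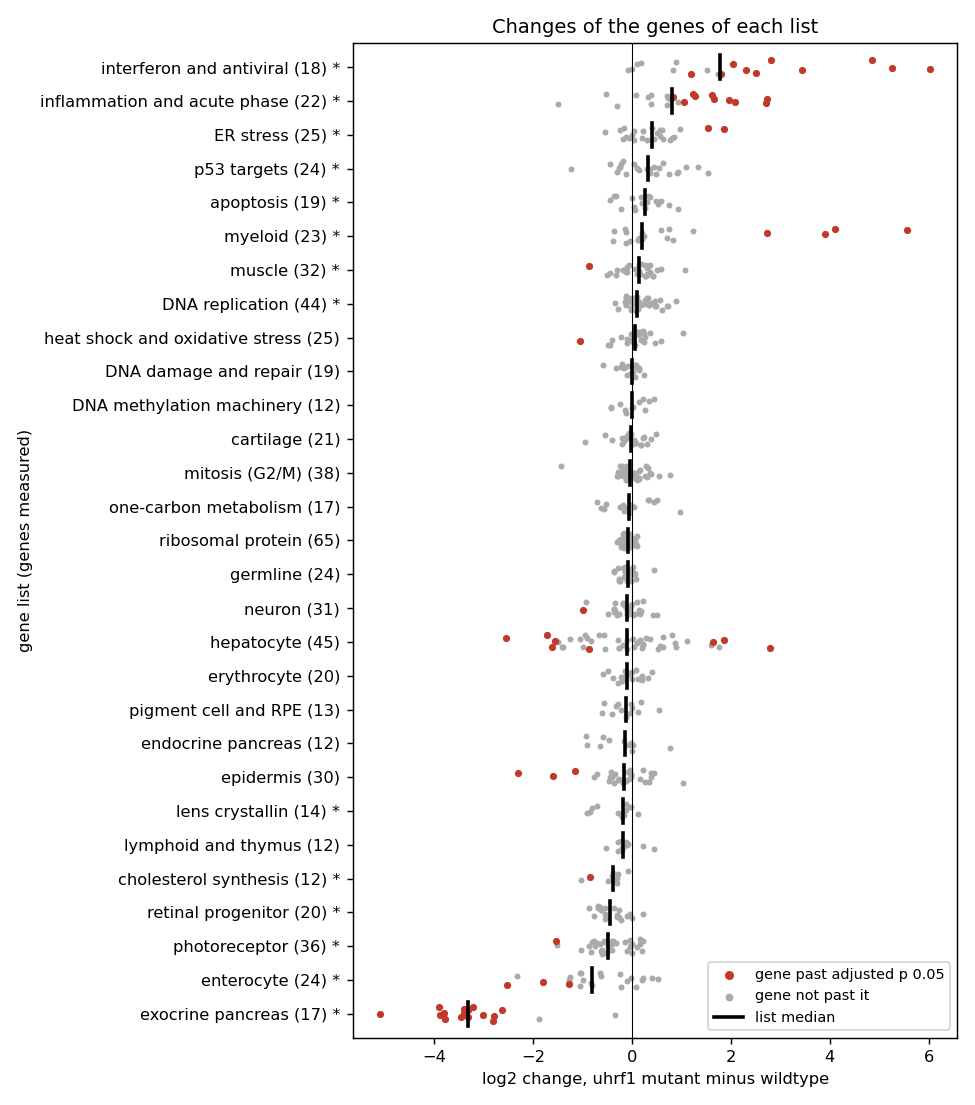
Log2 change (mutant minus wildtype, horizontal axis) of every measured gene of the 29 lists, each list a line with its number of measured genes, ordered by median. Red points are genes past a limma adjusted p of 0.05, grey points the others and black bars list medians. An asterisk marks the 14 lists called by camera at the preset correlation. With an estimated correlation 0 lists were called, but that setting also missed a simulated shift. The exocrine pancreas list lay lowest with a median of -3.31 and the interferon list highest at 1.77.

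The other lists were not called by camera. By fry's mixed test, of movement in either direction, the erythrocyte, epidermis, neuron and one-carbon lists passed, with adjusted p-values of 0.0035, 0.017, 0.022 and 0.035. The DNA methylation machinery had 0 of 12 genes past the limma threshold (1 at an unadjusted p under 0.05), a median of 0.01 and a camera adjusted p of 0.52. The smallest p in it belonged to the methyl-CpG binding gene mbd2, which changed by 0.45 ± 0.14 (SE, log2). Mitosis genes had 0 of 38 past it (5 unadjusted), and 1 lower without wildtype replicate 1. Their lead gene mad2l1, of the spindle checkpoint, changed by 0.76 ± 0.13 (SE, log2) and was the only one higher adjusted over the list alone. In the epidermis list 3 of 30 genes fell, among them the keratin gene krt1-19d by 5.07-fold, and adjusted over the list alone 5 fell and 1 rose. The epidermis list's camera adjusted p was 0.14, 0.014 without wildtype replicate 1 and 0.00087 when scaled on the controls, where its median was 0.34 with 6 genes higher and 3 lower, and 1 gene fell with a pseudocount of 16. One gene fell in each of the neuron list (neurod6b, a neuronal transcription factor, by 2.00-fold) and the heat shock and oxidative stress list (the catalase gene cat, by 2.09-fold), and their camera adjusted p-values were 0.52 and 0.31. With median centring 0 neuron genes passed. With any 1 array left out, or with a pseudocount of 16, 0 neuron genes passed. The heat shock count was 1 lower with a pseudocount of 16 and without wildtype replicate 1, 1 higher without mutant replicate 2, and 0 without either of the other arrays. By limma 0 genes passed in the lists for DNA damage repair, cartilage, erythrocytes, lymphoid cells and thymus, germ cells, ribosomal proteins, pigment cells and one-carbon metabolism, which had 19, 21, 20, 12, 24, 65, 13 and 17 measured genes. At an unadjusted p under 0.05 there were 1, 2, 4, 1, 1, 0, 3 and 6, and the lists' camera adjusted p-values were 0.96, 0.93, 0.78, 0.52, 0.64, 0.45, 0.61 and 0.93 in that order. There were 1 cartilage, 1 neuron and 1 heat shock gene lower adjusted over the list alone, and 0 for the methylation machinery, DNA damage repair, erythrocytes, lymphoid cells, germ cells, ribosomal proteins, pigment cells and one-carbon metabolism. Scaled on the hybridisation controls, between 1 and 17 genes of each list in this paragraph were higher. Camera's direction was up while the median lay below 0 in the mitosis, cartilage and one-carbon lists, and up while the mean lay below 0 in the DNA damage list.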

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

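The tests of leukocyte share, of whole-pancreas loss, of RNA degradation and of a common fold in the exocrine pancreas and in the liver were chosen after the log2 changes or control values they use had been seen, while the test of array scaling was written down before its values were computed. Its setting that scales on the hybridisation controls was itself added after seeing the data.

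Among the 4707 probe sets without exactly 1 gene symbol, which no list or named gene uses, 38 were higher and 10 lower in mutant larvae by limma at an adjusted p under 0.05. They are flagged only because the gene-level comparisons do not use these probe sets, of which 1.0% were called, against 1.7% of the 10795 with 1 gene symbol. The largest log2 changes among them were 4.43 and -4.39, and the second of these probe sets read 66.1 in mutants and 1409 in wildtype larvae.

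The rise of interferon list genes and of cd74a and cd74b could reflect more leukocytes in the mutant RNA, which these data leave open. The 35 genes of the myeloid and lymphoid lists, 6 of them also in other lists, had a median log2 change of 0.12 (95% bootstrap interval over genes -0.12 to 0.22), and the 13 brighter than the median gene in wildtype larvae had a median of 0.25 (-0.12 to 0.75). Neither median shows a common rise, but camera called the myeloid list upward at the preset correlation with an adjusted p of 4.6e-08 (0.35 with an estimated correlation). Without its antigen-presentation, chemokine and metalloprotease genes, a choice made after seeing the data, the myeloid median was 0.15. Camera at the preset correlation still called that shortened list upward, with an adjusted p of 0.0098. The explanation stays open because many members lay near the floor and the 13 leave out 3 of the 4 members past the limma threshold, cd74a, cd74b and mmp9. The interferon list's median was 1.28 to 2.26 under the 4 other scalings and pseudocounts tried, so none of these removed the rise. The lowest value came from the pseudocount of 16, which is not a scaling. The test was weak: quantile normalization and median centring put the median of all probe sets at -0.01 and 0.01, against -0.04 as deposited. They could therefore hardly have removed the rise. A changed state of the cells present, the mutation itself, and infection or housing that differed between the groups remain open and untested.

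The fall of exocrine pancreas genes was larger than that of the islet list, whose median was -0.14 (95% bootstrap interval -0.62 to -0.01), -0.33 without mutant replicate 2 and 0.01 without mutant replicate 1. The 7 islet genes brighter than the median gene in wildtype larvae had a median of -0.46 (-0.90 to -0.04). A fall of the islet list equal to that of the exocrine list is thus argued against and a smaller one is not. Of the 12 islet genes 2, pax6b and neurod1, are also in other lists, so in whole-larva RNA the list does not gauge islets alone. Whether islets were lost is not settled. The intervals run over genes and leave out the spread between arrays. A common fold of acinar tissue loss stays open: 15 exocrine genes with a mean wildtype intensity between 100 and 5000 had log2 changes from -5.09 to -1.89, with an SD over genes of 0.72 against a median SE of 0.19 (heterogeneity p 6.3e-25), but they all lay below 0, and compression of folds by the array may spread them in that way. RNA degradation could not be settled either. Degradation in the mutant samples would raise the log2 ratio of 3' over 5' signal, and neither control showed this. The ratio was instead lower in mutants by less than its spread, at -0.52 with a pooled SD of 0.54 for actin and -0.24 with a pooled SD of 0.30 for GAPDH.

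For the liver, calls in both directions argue against a uniform change in tissue share as the only change. A change in share combined with other changes is not argued against. The 30 hepatocyte genes with a mean wildtype intensity between 100 and 5000 had log2 changes from -2.55 to 1.87. Genes past the limma threshold lay in both directions, and the SD was 1.098 against a median SE of 0.27 (heterogeneity p 9.3e-108). The full list shares genes with other lists, such as rbp2a and hp, so it does not gauge the liver alone. The pattern was picked from these same calls, which the test needs for its verdict. Its outcome was thus largely fixed beforehand, and the test adds no separate support to them. This p and that of the exocrine genes treat genes of the same arrays as independent and SEs from 2 arrays per group as known. Both p-values therefore overstate the evidence. An acute-phase response of hepatocytes is an open hypothesis that was not tested. In the inflammation and acute-phase list hp changed by -1.50, crp by -0.30, saa by 0.39 and c3a.1 by 0.74 (log2), none past the limma threshold. These genes were chosen after their values were seen.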

How the results depend on the processing

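Scaling on the hybridisation controls and the shortened myeloid list were chosen after seeing the data, and causes were not tested unless stated. The 176 genes (91 higher, 85 lower; 233 probe sets) became 288 (139, 149; 394) with an intensity-dependent robust prior, 309 (144, 165; 419) at an adjusted p under 0.10, 66 (34, 32; 80) with a pseudocount of 16, and 2833 (2754, 79; 5223) when scaled on the hybridisation controls, which shifts every gene upward. The unmoderated limma model called 0 genes (0, 0; 0 probe sets), with 868 at an unadjusted p under 0.05 and a smallest adjusted p of 0.33. Leaving out 1 array gave 113 to 220 genes, 68 to 102 higher, 43 to 118 lower and 154 to 310 probe sets, where the lone array of a group was assumed to vary like the other group. Of the 176 genes, 85 (52 higher, 33 lower) passed in all 4 of these fits and 176 had the same direction in each. The other alternatives gave 153 to 239 genes. The uhrf1 change did not pass in any of these for which it was computed, which leaves out the mean of all probe sets. It was -0.73 to -0.11 with 1 array left out, and reversed to 0.069 when scaled on the controls, as did, of the 63 other named genes, bada (0.039), cahz (0.0057), fdps (0.10) and rpl22 (0.20), none of them past the threshold. The pseudocount of 16 ended the call of 11 of the 63. Quantile normalization ended 4 and added 1, median centring ended 3 and added 2, and scaling on the controls ended 3 and added 14. The robust prior added 6 and the dim filter 4, and leaving out any array also ended some.

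The 14 called lists became 0 with an estimated correlation, 2 by fry (interferon and exocrine pancreas) and 11 to 14 with 1 array left out. Quantile normalization, median centring, the dim filter, the pseudocount, the mean of probe sets and camera on ranks each kept all 14, and scaling on the controls kept 11. With an estimated correlation the adjusted p was 0.28 for interferon, inflammation, exocrine pancreas, p53, photoreceptor and retinal progenitor lists, 0.31 for endoplasmic reticulum stress, 0.35 for myeloid and cholesterol, 0.44 for enterocyte and apoptosis, 0.56 for replication and lens, and 0.79 for muscle. As that setting called no list and missed the simulated shift, these values do not argue against a shift. Fry's was 0.058 for inflammation, p53 and photoreceptor, 0.098 for myeloid, 0.11 for retinal progenitor, 0.13 for endoplasmic reticulum stress and cholesterol, 0.22 for enterocyte and lens, 0.31 for apoptosis, 0.46 for replication and 0.78 for muscle. When scaled on the controls, p53 (0.059), apoptosis (0.055) and muscle (0.31) lost the call, and hepatocyte (2.0e-05), islet (0.043) and epidermis (0.00087) gained it, as epidermis also did with the robust prior (0.041). With 1 array left out, adjusted p-values ran from 8.8e-06 to 0.051 for replication, 0.00030 to 0.11 for apoptosis, 0.0068 to 0.12 for lens, 0.0016 to 0.49 for muscle, 0.044 to 0.64 for islet and 0.014 to 0.53 for epidermis.

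Fry's direction is not relative to the other genes. It was down for DNA damage repair (adjusted p 0.80), cartilage and one-carbon (both 0.78), where camera's was up and the list means lay below 0. Lists that were not called changed camera's direction without passing. With adjusted p, these were DNA damage repair (0.99) and hepatocyte (0.99) without the dim probe sets, and hepatocyte with the pseudocount of 16 (0.95). Scaled on the controls, they were cartilage and one-carbon (both 0.49), erythrocyte (0.95), germ cell (0.59) and ribosomal protein (0.13). With 1 array left out the direction also changed for methylation machinery (0.11 to 0.72), DNA damage repair (0.50 to 0.80), hepatocyte (0.075 to 0.53), cartilage (0.091 to 0.99), erythrocyte (0.12 to 0.87), lymphoid (0.20 to 0.94), germ cell (0.13 to 0.82), pigment cell (0.095 to 0.73) and one-carbon (0.37 to 0.79). Signal close to background limits what dim genes can show. No paired analysis was possible because only 1 replicate number is shared between the groups.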

Other observations

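The genes named in this part, other than krt1-19d, were chosen after their values were seen. Called genes outside the 29 lists included the proteasome activator subunits psme1 and psme2, which rose by 2.89 ± 0.19 and 3.05 ± 0.13 (SE, log2), the proteasome subunits psmb12 and psmb13a, which rose by 2.28 ± 0.16 and 2.05 ± 0.20, and the MHC class I gene mhc1ufa, which rose to 142 intensity units. Its wildtype level of 10.7 lay under the 12.6 that bounds the dimmest 25% of probe sets, so no fold is given for it. The limma adjusted p-values of these 5 genes ran from 0.00034 to 0.0098. Some relatives of the same families also passed and others did not, among the latter with log2 changes of 0.11 for psmb5, -0.03 for psmb6, 0.10 for psme3, 0.05 for mhc1uda and -0.02 for mhc1uka, and members of these families can cross-hybridise. No list of such genes was fixed and no enrichment was tested.

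In the epidermis list the keratin genes krt97 and krt15 fell with krt1-19d, with log2 changes of -1.60 and -1.16 and limma adjusted p-values of 0.0086 and 0.044.

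The 18 hybridisation controls had log2 changes from -0.82 to -0.06 and a median of -0.50. The ratio of 3' over 5' signal for actin was 26.8 and 15.8 on the mutant arrays and 38.6 and 22.6 on the wildtype arrays.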
